A study of Rattus norvegicus with 252 samples.

How the data were processed

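RNA was sequenced from the striatum, cortex, hippocampus and cerebellum of 60 Long Evans rats of both genotypes and sexes at 2, 6 and 12 months. Per the labels' protocols, tissues were flash frozen, total RNA was extracted with a Qiagen kit and checked on an Agilent Bioanalyzer, and Illumina libraries were made from enriched RNA subfractions of at least 3.75 ug of RNA. The aligner, the counting program and the genome build are not given in the sources used here. The authors deposited a table of estimated counts, or expected counts, for 32883 genes with Ensembl rat identifiers and 1 column per library. Per the file's values these are not all whole numbers and their totals differ between libraries, so they were rounded to whole numbers before testing. The authors also deposited a table whose name says FPKM, but every column has the same total, that of TPM values, so its values are on the TPM scale. It was not used for any result. Tables of transcripts were not used here, since their identifiers are not paired with genes in the files.

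Columns were matched to samples through the identifiers in the labels. For the 12 animals sequenced in both batches, the count table holds a pair of columns whose names differ by a separator, and the column written with dots was taken as the repeat library of batch 2. No label states this, so it is an inference from the column names. It was checked on a mean log2 contrast over the 200 genes that differed most between 12-month and younger libraries of the other tissues. First libraries lay between -0.99 and -0.22, repeat libraries between -0.36 and 0.30 and 12-month libraries of batch 2 between 0.22 and 0.81, so the ranges of first and repeat libraries overlapped slightly. These genes were chosen on a contrast in which age and batch change together, so the check is a limited one. No per-sample columns of the gene tables were left unused. None of the identifiers matched the table of reference gene names (0 of 32883), so the gene lists fixed beforehand, which are written as gene symbols, were not tested, and it was not determined which of the tested genes is the targeted one.

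Groups came from the labels for tissue, genotype, age, sex and batch. Libraries of the same animal were known from the identifiers. The replicates of a group are separate animals. Replicate numbers within sex were shared between genotypes, but no source says that they pair animals. No pair of libraries in a group agreed to within counting noise. The median squared difference between libraries of a group was at least 2.62 times that of counting noise, with a median of 5.32 over pairs, and 2.84 to 14.3 times between the first and repeat libraries of a label.

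Each comparison of genotypes used the 20 study libraries of a tissue and age with sex as a covariate, in edgeR 4.0.16 under R 4.3.3: filterByExpr, TMM normalization, robust dispersion estimates and the quasi-likelihood F test, with genes called at a Benjamini-Hochberg adjusted p under 0.05. These choices, with the interaction tests of genotype by age, by tissue and by sex, the batch and ageing comparisons and the first group of alternatives, were fixed before the data were examined. Interactions by age and by sex used the 60 study libraries of a tissue. Those by tissue used the libraries of an age with the animal as a block. Log2 CPM values used a prior count of 2 and genes with at least 10 counts per library on average. Values of CPM were computed from the deposited counts with TMM library sizes. Standard errors belong to the log2 fold changes of edgeR, and intervals have a confidence level of 95%.

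Genes were to be named by a fixed rule: the targeted gene, the called genes with the largest and smallest log2 fold changes among those with a gene symbol and a mean of at least 1 CPM, and members of fixed lists with the smallest adjusted p. Because the rule needs symbols, it named no gene, and the 3 identifiers in the text were chosen after their values had been seen, as the genes called in the summed counts of the animals. Groups of genes enriched in a tissue were also chosen after seeing the data. A gene belonged to a tissue when its mean in WT libraries of that tissue was at least 2 log2 units above each other tissue and above 0 log2 CPM. The groups from 2 months held 100 striatal, 54 cortical, 54 hippocampal and 273 cerebellar genes and those from 6 months 103, 50, 55 and 289, with 87, 45, 46 and 244 shared. Comparisons at 2 months used the groups from 6 months and the others those from 2 months, so that no group was chosen on the libraries it was tested in. They were tested with camera at a preset inter-gene correlation of 0.01 and with an estimated one, and with fry, in limma 3.58.1. Every set call made with the preset correlation was lost with an estimated one. Scores per library were tested by enumerating all permutations of genotype within sex, two-sided, with Benjamini-Hochberg adjustment over all tissues, ages and groups.

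Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, limma-voom with the first part of the animal identifier as a random effect, relative log expression size factors (RLE), no filter on low counts, a stricter filter of 1 CPM, no sex covariate, the replicate number as a block, 1 fit over the 60 libraries of a tissue and leaving out each library. Chosen after seeing the data were the fits without 9 libraries whose median correlation with their tissue was under 0.97, library quality weights, the exchange of the first and repeat libraries of the repeated males, the sums over tissues, the gene groups, the scores and the choice of genes that differ between animals, with and without striatal libraries. Each count was also compared with counts from other splits of the same samples, at most 100 per comparison. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

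Depth was 25.3 to 50.8 M counts per library. The methods were tested on simulated data with the means, library sizes and dispersions of the real libraries and known changes. For the striatum at 2 months, edgeR recovered 77.6% of genes changed by 1.25-fold, 95.5% by 1.5-fold and 100% by 2-fold among 15423 genes. For the striatum at 12 months it recovered 28.4, 61.2 and 92.4% at those folds among 15330 genes, and for the cerebellum at 12 months 73.1, 89.6 and 95.5% among 15094. For the sums over tissues it recovered 97.0, 95.5 and 100% among 17375 genes. In the simulation of the striatum at 12 months, 4 of 125 genes called by edgeR and 24 of 161 called by DESeq2 had not been changed.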

Results

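Gene expression was measured by RNA sequencing in the striatum, cortex, hippocampus and cerebellum of Long Evans rats that were either wild type (WT) or heterozygous for the Q130 knock-in, an allele with a lengthened glutamine-coding repeat made to model Huntington disease. That inherited disease damages the striatum, a forebrain region that controls movement, before other brain regions. The animals were 2, 6 or 12 months old. Each of 60 animals gave all 4 tissues, so that the 240 study libraries fell into 24 groups of 10, each with 5 females and 5 males. Another 12 libraries were repeats of the striatum of 12 males aged 2 or 6 months, 3 per age and genotype, and were sequenced in a later batch. All study libraries of 2 and 6 months belonged to batch 1, and all of 12 months, with the repeats, to batch 2, so each comparison of genotypes at 1 age lay within 1 batch.

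Total counts per library ran from 25.3 to 50.8 M with a median of 34.3 M, and 17793 to 18729 of the 32883 listed genes were detected. Tissue set the main axes of variation. The first 3 principal components held 48.1, 18.8 and 8.87% of the variance, and tissue explained 99.8, 93.1 and 95.9% of them, while genotype explained at most 1.67% of any of the first 6. The median correlation of a library with the others of its tissue was typically 0.985. It lay between 0.859 and 0.962 in 9 libraries of 7 animals, against 0.973 or more in all others. Of these 9 libraries that stood apart, 8 carried the Q130 label and 1 the WT label. The lowest values belonged to the libraries labelled striatum of Q130 male 3 (0.859) and cortex of Q130 male 4 (0.895) at 12 months. In 3 libraries the correlation was higher with another tissue. The library labelled striatum of Q130 male 1 at 6 months correlated at 0.938 with striatal and at 0.986 with hippocampal libraries. The library labelled hippocampus of Q130 male 5 at 6 months correlated at 0.932 with hippocampal and at 0.983 with striatal libraries. The library labelled striatum of Q130 female 2 at 12 months correlated at 0.961 with striatal and at 0.976 with hippocampal libraries. Counts are therefore also given without these 9 libraries, a choice made after the data had been seen. The files do not pair gene identifiers with names, so genes are described through groups defined by tissue and age, and 3 are given by identifier. These 3 were chosen after their values had been seen. No identifier was matched to a name, and whether the targeted gene is among these 3 was not determined.

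The first question was which striatal genes differ between Q130 and WT rats at each age. In the striatum at 2 months, 182 genes were higher and 211 lower in Q130 rats, 393 of 15500 tested (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, 10 libraries per genotype). The changes were small, with a median absolute log2 fold change of 0.18 among the called genes, a range from -1.10 to 0.70, and 5 genes beyond 1.5-fold. ENSRNOG00000011073 fell from 159 ± 4.01 CPM (SD, n = 10) in WT to 118 ± 8.16 CPM (SD, n = 10) in Q130 striatum, a log2 fold change of -0.43 ± 0.03 (SE, edgeR adjusted p = 4.57e-08). ENSRNOG00000005700 rose from 216 ± 11.1 to 244 ± 9.79 CPM (SD, n = 10 each), a log2 fold change of 0.17 ± 0.03 (SE, edgeR adjusted p = 0.0126). Genes with much higher levels in the striatum than in the other tissues of WT rats mostly had higher estimates in Q130 striatum. Of 103 such genes, chosen from the libraries of 6 months, 92 had a higher estimate, with a median log2 fold change of 0.15, and 18 were called over all genes. The group differed from other genes by camera with a preset correlation (adjusted p = 1.71e-17), but not with an estimated one (adjusted p = 0.733 with an estimated correlation). Of 24 cortex-enriched genes measured in the striatum, 18 had a lower estimate, with a median of -0.20 (camera adjusted p = 0.00137; adjusted p = 0.733 with an estimated correlation). The count of 393 ranged from 79 to 1159 when single libraries were left out, without the libraries labelled Q130 male 3 and Q130 male 5, respectively. DESeq2 called 1013 genes and limma-voom with library quality weights 1421. The count was 1 when all 60 striatal libraries shared a fit, where ENSRNOG00000011073 remained called (edgeR adjusted p = 1.89e-06) and ENSRNOG00000005700 was not (0.17 ± 0.06 SE, edgeR adjusted p = 0.795).

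At 6 months no striatal gene passed edgeR's test among 15569, with 599 at an unadjusted p under 0.05, and limma-voom called 0 and DESeq2 2. ENSRNOG00000011073 was at 148 ± 11.1 CPM in WT and 119 ± 12.6 CPM in Q130 striatum (SD, n = 10 each; edgeR adjusted p = 0.39). Without the library labelled Q130 male 1, it was the 1 gene called, with a log2 fold change of -0.36 ± 0.04 (SE, edgeR adjusted p = 3.42e-05). The same library set the estimates of whole groups of genes. All 100 striatum-enriched genes had lower estimates with it, with a median of -0.36, whereas 51 were higher and 49 lower without it, with a median of 0.01. The 95% confidence interval of the fold change lay inside 1.5-fold in both directions for 92.6% of the 14120 genes at 1 CPM or more.

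At 12 months no striatal gene passed edgeR's test among 15426, with 1505 at an unadjusted p under 0.05, and limma-voom called 0 and DESeq2 5. ENSRNOG00000011073 was at 156 ± 16.9 CPM in WT and 116 ± 12.3 CPM in Q130 striatum (SD, n = 10 each), a log2 fold change of -0.42 ± 0.07 (SE, edgeR adjusted p = 0.0821). Without the libraries labelled Q130 female 2 and Q130 male 3, which stood apart from the striatum, it was again the 1 gene called, at -0.46 ± 0.06 (SE, edgeR adjusted p = 0.000859). Striatum-enriched genes leaned toward lower estimates in Q130 rats, 92 of 100 with a median log2 fold change of -0.34 in all libraries and 77 of 100 with a median of -0.09 without those libraries. The second value passed camera with a preset correlation (adjusted p = 8.07e-06) and not with an estimated one (adjusted p = 0.793 with an estimated correlation). Here 82.1% of genes at 1 CPM or more had an interval inside 1.5-fold, the lowest share of the 12 comparisons. A fit over all 60 striatal libraries, which kept those that stood apart, called 673 genes at this age, 600 of them higher in Q130 rats.

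Averaged per library, the striatum-enriched genes had a higher mean in Q130 than in WT rats at 2 months and a lower one at 12 months, but neither difference passed after adjustment over all tissues, ages and gene groups. At 2 months their mean was 4.10 ± 0.09 log2 CPM in WT and 4.26 ± 0.09 in Q130 rats (SD, n = 10 each), and 10 of 10 Q130 libraries lay above the WT median (difference 0.16, two-sided exact permutation p = 0.00195, adjusted p = 0.0937). At 12 months the mean was 4.12 ± 0.10 in 10 WT libraries and 4.02 ± 0.07 (SD) in the 8 Q130 libraries that did not stand apart, with 0 of them above the WT median (difference -0.10, two-sided exact permutation p = 0.0439, adjusted p = 0.385). With all 10 Q130 libraries the difference was -0.35 (exact permutation p = 0.0112, adjusted p = 0.269). At 6 months it was -0.03 without the library that stood apart (exact permutation p = 0.593). The genotype effect at 12 months minus that at 2 months was -0.51 over all 40 libraries (two-sided exact permutation p = 5.23e-05) and -0.25 over the 38 that remained (exact permutation p = 0.000218). This test was chosen after the pattern had been seen, and its p is not adjusted. Each effect was taken within its own batch, but age and batch changed together between them. At 12 months the genotypes shared no first part of the animal identifier, so a difference that follows it cannot be told from genotype. The scores also used different gene groups, 103 genes at 2 months and 100 at 12 months, with 87 shared.

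**Figure D1:**
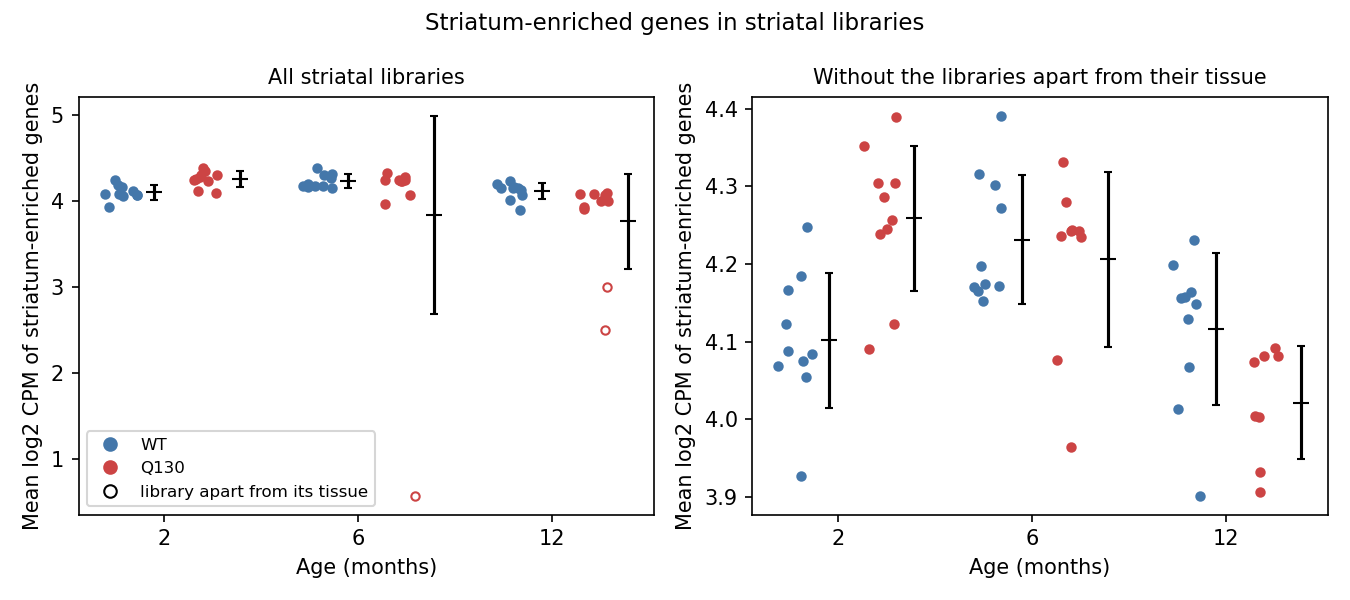
Mean log2 CPM of striatum-enriched genes in each striatal library (points, WT blue and Q130 red) by age in months, with the mean and SD of each group as bars, for all libraries on the left and without those that stood apart from their tissue (open circles) on the right, where the vertical axis covers a narrower range. Without them, Q130 libraries averaged 4.26 against 4.10 in WT at 2 months and 4.02 against 4.12 at 12 months.

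In the cortex, which sends the main input to the striatum, the same questions gave 1 called gene. At 2 months ENSRNOG00000011073 fell from 193 ± 11.1 to 146 ± 14.5 CPM (SD, n = 10 each), a log2 fold change of -0.40 ± 0.05 (SE, edgeR adjusted p = 0.00109), and was the 1 gene called of 15504 tested, with 358 at an unadjusted p under 0.05. limma-voom and DESeq2 also called 1 each, whereas a fit over all 60 cortical libraries called 0, with an adjusted p of 1 for this gene and 169 genes at an unadjusted p under 0.05. That fit kept the cortical libraries of 6 and 12 months that stood apart, and whether they lowered the count was not tested. At 6 months edgeR's test called 0 of 15509 genes with 964 at an unadjusted p under 0.05, as did limma-voom and DESeq2. Without the library labelled WT male 4, where ENSRNOG00000011073 was at 72.3 CPM, that gene was called at -0.38 ± 0.05 (SE, edgeR adjusted p = 0.000345), against -0.28 ± 0.13 (SE, adjusted p = 0.708) with it. At 12 months the test called 0 of 15275 genes with 618 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 1. Of 76 striatum-enriched genes measured in the cortex at 12 months, 50 had lower estimates, with a median of -0.06 (camera adjusted p = 0.0176; adjusted p = 0.733 with an estimated correlation).

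In the hippocampus edgeR's test called no gene at any age, 0 of 15466, 15472 and 15317 genes at 2, 6 and 12 months, with 949, 519 and 716 at an unadjusted p under 0.05. limma-voom called 0 at each age, DESeq2 1, 0 and 1, limma-voom with library quality weights 1, 2 and 0, and a fit over all 60 hippocampal libraries 0, 2 and 0. Levels of ENSRNOG00000011073 were nevertheless below those of WT rats at each age, at 168 ± 21.1 against 214 ± 8.02 CPM at 2 months, 158 ± 29.5 against 199 ± 18.4 at 6 months and 167 ± 10.9 against 199 ± 24 at 12 months (SD, n = 10 each), with edgeR adjusted p of 0.076, 0.989 and 0.86. At 6 months 53 of 54 hippocampus-enriched genes had lower estimates with a median of -0.33, and 78 of 82 striatum-enriched genes had higher estimates with a median of 0.33. Both medians were 0 without the 2 libraries that stood apart, 1 of them the hippocampal library with a striatal profile. At 2 months 25 of 32 cortex-enriched genes had higher estimates in Q130 hippocampus, with a median of 0.12 (camera adjusted p = 0.013; adjusted p = 0.733 with an estimated correlation).

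In the cerebellum, a region less affected in Huntington disease, edgeR's test with all libraries made its calls at 6 and 12 months. At 12 months 131 genes were higher and 107 lower in Q130 rats, 238 of 15177, with a median absolute log2 fold change of 0.22, a range from -0.83 to 1.26, and 18 genes beyond 1.5-fold. At 6 months 7 were higher and 37 lower, 44 of 15305, with a median of 0.24. At 2 months edgeR's test called 0 of 15349 genes with 244 at an unadjusted p under 0.05, limma-voom and DESeq2 called 0, and 2 genes were called, with 1324 at an unadjusted p under 0.05, without the libraries labelled Q130 male 1 and male 2, which stood apart. ENSRNOG00000010867 fell from 2.00 ± 0.389 to 1.20 ± 0.299 CPM at 6 months (log2 fold change -0.74 ± 0.16 SE, edgeR adjusted p = 0.0493) and from 1.85 ± 0.567 to 1.02 ± 0.288 CPM at 12 months (-0.83 ± 0.17 SE, edgeR adjusted p = 0.0232; SD, n = 10 each). ENSRNOG00000011073 fell from 243 ± 24.5 to 173 ± 11.3 CPM at 6 months (-0.49 ± 0.06 SE, edgeR adjusted p = 7.13e-05) and from 224 ± 26.6 to 158 ± 17.9 CPM at 12 months (-0.50 ± 0.07 SE, edgeR adjusted p = 0.00485). ENSRNOG00000005700 rose from 468 ± 22.7 to 528 ± 30.9 CPM at 6 months (0.17 ± 0.04 SE, edgeR adjusted p = 0.0493). The calls of ENSRNOG00000010867 and ENSRNOG00000005700 at 6 months lay at the threshold and passed in 6 and 8 of 30 other fits, with adjusted p up to 0.192 and 0.208, against 30 of 30 for ENSRNOG00000011073; DESeq2 gave no adjusted p for ENSRNOG00000010867.

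The calls at 6 and 12 months in the cerebellum, made in different animals, overlapped. Among 15133 genes tested at both ages, 9 of the 37 lower at 6 months were among the 107 lower at 12 months, where 0.262 would be shared by independent lists (Fisher's exact p = 3.31e-12), and 2 of the 7 higher at 6 months were among 130 higher at 12 months, where 0.0601 would be shared (Fisher's exact p = 0.0015). Fisher's test takes genes as independent, which correlated genes are not, so these p-values overstate the evidence. The genotypes shared no first part of the animal identifier at 12 months and hardly any at 6 months. The labels do not say what it stands for, and a difference that follows it cannot be told from genotype at these ages. The correlation of cerebellar libraries that share it was estimated at 0.0476 and -0.0247 at 6 and 12 months, which bears only on spread within a genotype. With limma-voom 4 of 9 lower genes were shared (0.0654 by independent lists) and 0 higher, with 1 fit over the 60 libraries 1 of 2 lower and 0 of 1 higher, and with DESeq2 47 of 287 lower (7.07 by independent lists) and 20 of 92 higher (2.64). Of 273 cerebellum-enriched genes, 163 had lower estimates in Q130 rats at 12 months with a median of -0.02, and 24 were called (camera adjusted p = 0.0176; adjusted p = 0.733 with an estimated correlation). Leaving out single libraries gave 50 to 446 calls at 12 months, without the libraries labelled WT male 4 and WT female 1, and 4 to 471 at 6 months, with the highest count without WT male 5. A fit over all 60 cerebellar libraries called 45 genes at 12 months and 3 at 6 months, limma-voom called 9 and DESeq2 385 at 6 months, and DESeq2 called 659 at 12 months.

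A comparison added after these results asked which genes differed across the whole set of tissues, with the counts of each animal summed over its 4 tissues and age and sex as covariates. It called 3 of 17416 genes in 30 WT and 30 Q130 animals, 1 higher and 2 lower in Q130 rats. Without a filter on low counts it called 10 of 25146 genes, 8 higher and 2 lower. limma-voom called 3 and DESeq2 4. ENSRNOG00000011073 fell from 194 ± 16.4 to 149 ± 6.41 CPM (SD, n = 30 each), a log2 fold change of -0.38 ± 0.03 (SE, edgeR adjusted p = 1.96e-16), and 30 of 30 Q130 animals lay below the WT median. It was lower in Q130 rats in 12 of 12 comparisons of tissue and age, by -0.50 to -0.25, and was called in 4. ENSRNOG00000010867 fell from 3.63 ± 0.336 to 3.01 ± 0.413 CPM (log2 fold change -0.28 ± 0.04 SE, edgeR adjusted p = 2.75e-06), with 28 of 30 Q130 animals below the WT median and lower values in 11 of 12 comparisons. ENSRNOG00000005700 rose from 268 ± 13 to 287 ± 18.4 CPM (0.10 ± 0.02 SE, edgeR adjusted p = 0.0261), with 28 of 30 Q130 animals above the WT median and higher values in 10 of 12 comparisons. These genes were chosen on the sums of the same libraries, so their agreement over animals and comparisons is partly built in.

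**Figure D2:**
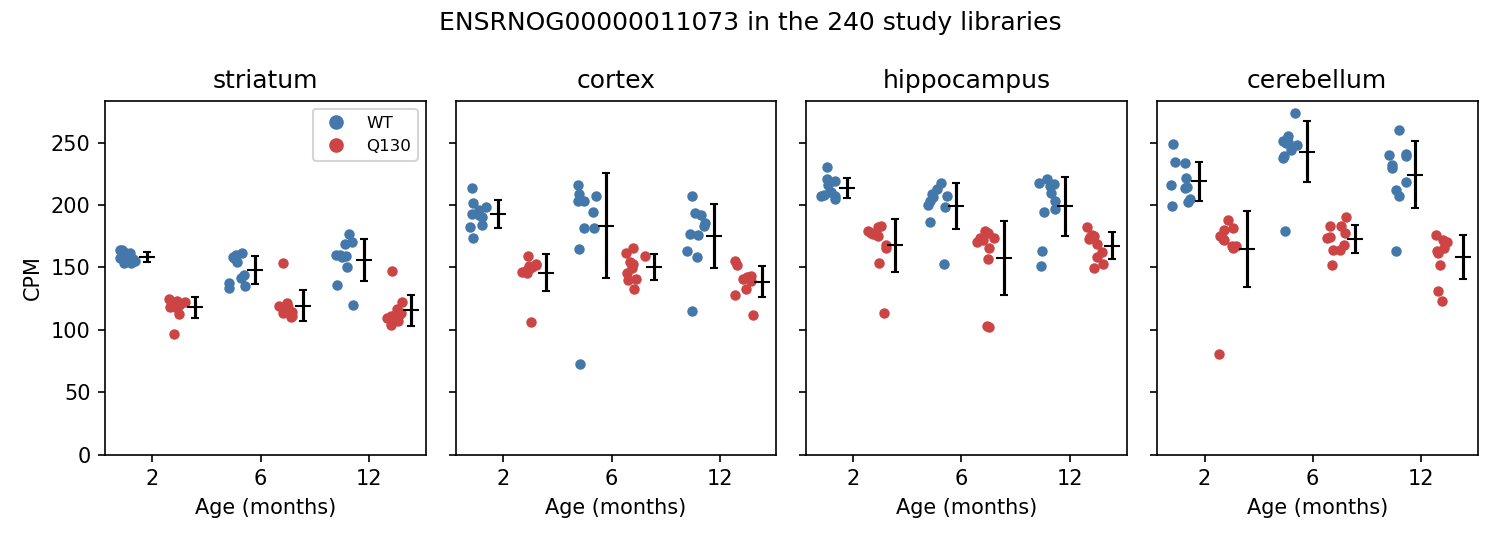
Level of ENSRNOG00000011073 in CPM in each of the 240 study libraries (points, WT blue and Q130 red) by tissue and age in months, with the mean and SD of each group as bars. Q130 means lie below WT means in 12 of 12 comparisons, as in the striatum at 2 months, with 118 against 159 CPM.

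Whether the genotype effect changed with age was tested within each tissue. In the striatum 11 of 16113 genes had a different genotype effect at 12 than at 2 months, 4 with a higher and 7 with a lower effect at 12 months, with a median absolute log2 difference of 0.51, and 775 did without the 2 libraries of 12 months that stood apart and the 1 of 6 months, 409 higher and 366 lower. Between 6 and 2 months edgeR's test called 0 striatal genes with 923 at an unadjusted p under 0.05 and limma-voom 0, and 73 were called without the same libraries, 59 of them higher. Between 12 and 6 months it called 0 with 2020 at an unadjusted p under 0.05, and limma-voom called 0. In the cerebellum 1 of 15866 genes had a lower effect at 12 than at 2 months, by a log2 difference of 1.14, and 221 differed without the libraries that stood apart, 128 higher and 93 lower. limma-voom called 6 in the striatum at 12 against 2 months and 0 in the cerebellum. In the cortex and hippocampus both edgeR's test and limma-voom called 0, with 805 and 784 genes at an unadjusted p under 0.05 by edgeR. Ages 2 and 12 months belonged to different batches, and at 12 months the genotypes shared no first part of the animal identifier.

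Whether the genotype effect in the striatum differed from the mean effect in the other tissues of the same animals was tested at each age. At 2 months 22 of 16597 genes differed, 8 with a higher and 14 with a lower effect in the striatum, with a median absolute log2 difference of 0.29, and 124 did without the cerebellar libraries that stood apart. limma-voom called 5. At 6 and 12 months edgeR's test called 0, with 453 and 1805 genes at an unadjusted p under 0.05, and limma-voom called 0 at both ages. Without the libraries that stood apart, 6 genes were called at 12 months, 1 with a higher and 5 with a lower effect in the striatum. Differences of the genotype effect between females and males were not called for any gene in any of the 4 tissues by edgeR's test or limma-voom. By edgeR, 556 genes were at an unadjusted p under 0.05 in the striatum, 528 in the cortex, 416 in the hippocampus and 603 in the cerebellum.

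Ageing in WT rats was compared between 6 and 2 months, both within batch 1. WT rats of these ages shared no first part of the animal identifier, so a difference that follows it cannot be told from age. In the striatum 1294 genes were higher and 1364 lower at 6 months of 15539 tested, with a median absolute log2 fold change of 0.22 among those called. The hippocampus had 1319 higher and 1324 lower genes with a median of 0.20, and the cerebellum 1466 higher and 1568 lower with a median of 0.22. The cortex had 259 higher and 291 lower genes, 550 in all, or 1688 without the library labelled WT male 4 that stood apart. Of 14641 genes tested in all 4 tissues, 64 were higher and 99 lower in all 4, and 176 of the 5949 called in any tissue had opposite signs in different tissues. These shared counts rest on the 550 cortical calls, and without the cortical library that stood apart they were 109 higher and 195 lower of 14651. Among batch 2 striatal males, 812 of 15589 genes differed between 12-month libraries and the repeat libraries labelled 6 months, 481 higher and 331 lower at 12 months, and 4056 did without the male library of 12 months that stood apart. The repeats labelled Q130 male 2 and WT male 2 were closest to first libraries of 2 months, at correlations of 0.92 and 0.95 (described below). This comparison may thus set 12 months against a mix of 6 and 2 months.

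The repeat libraries were made to compare the batches. Between the 12 first and 12 repeat libraries, with the labelled animal as a block, 178 genes were higher and 455 lower in batch 2, 633 of 15425, with a median absolute log2 fold change of 0.25. Without that block, 341 were higher and 581 lower, 922 in all. Genotype gave 1 called gene among these 12 males in batch 1, ENSRNOG00000011073, at -0.37 (860 genes at an unadjusted p under 0.05), a count that was 0 without the library labelled Q130 male 1 or that labelled WT male 4 of 2 months and 2 and 3 without those labelled WT male 2 and WT male 5 of 6 months. In batch 2 the genotype labels of the repeats gave 0 (306 genes at an unadjusted p under 0.05, edgeR's test). The closest first library carried the other genotype for 6 of the 12 repeats, so this 0 does not bear on the genotype effect. On the log2 CPM scale, ENSRNOG00000011073 differed by -0.36 between the genotypes in the first libraries, with the lowest WT value of 7.06 above the highest Q130 value of 6.91 (n = 6 each, two-sided exact permutation p = 0.00216), and by -0.05 between the genotype labels in the repeats (exact permutation p = 0.758).

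Over 42 genes whose levels differed between animals and were alike across an animal's tissues, 239 of 240 study libraries were closest to the other tissues of their own animal, and all 12 first libraries were, which is partly built in because the genes were chosen on these libraries. Of the 12 repeat libraries, 2 were closest to the first library of their own label. Each of the 12 was closest to a different first library, with a highest correlation of 0.90 to 0.97 and a second highest of at most 0.78. The closest library carried the other genotype in 6 cases and the other age in 4. With 46 genes chosen from the other tissues alone, without any striatal library, 59 of 60 striatal study libraries and 12 of 12 first libraries were closest to their own animal, and each of the 12 repeats had the same closest first library as before. Values from the repeat libraries, with the comparison of batches and that of ages in batch 2, are therefore given under their labels only, and the study libraries were used for the comparisons of genotypes above.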

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

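The tests on repeat libraries, on libraries out of place and on regional content were chosen or revised only after the results they bear on had been seen, as were the sums over tissues and the gene scores. The bounds for library size and for the regional content of the cerebellum were written before those tests were run, and the comparison with other splits was set beforehand. Libraries far from the rest of their group were sought by the gap of the highest or lowest value to its neighbour, and chance alone would flag about 1 in 20 groups. That rate assumes normally distributed values. For correlations only a gap at the lowest value was flagged, so under that assumption chance would flag fewer. Values stood apart in 12 of 24 groups for the correlation of a library with its tissue, in 2 for total counts and in 20 for the 3 genes given by identifier, 34 of 120 in all.

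The correlation with the other libraries of the tissue lay below the rest of the group, though in some cases close to the typical value over all libraries, 0.985. At 2 months it did so in the cortex of Q130 male 4 (0.977) and the hippocampus of Q130 female 5 (0.973). At 6 months it did so in the cerebellum of Q130 female 5 (0.982) and WT male 5 (0.985), the cortex of WT male 4 (0.922), the library labelled hippocampus of Q130 male 5 (0.932) and WT male 3 (0.978) and the library labelled striatum of Q130 male 1 (0.938). At 12 months it did so in the cortex of Q130 male 4 (0.895), the hippocampus of Q130 male 1 (0.982) and WT male 5 (0.982) and the striatum of Q130 male 3 (0.859). Total counts were high in the hippocampus of Q130 male 3 (43.7 M counts) and the striatum of WT female 3 (45.3 M counts), both at 6 months.

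Libraries are named by their labels throughout, and those labelled striatum of Q130 male 1 and hippocampus of Q130 male 5 at 6 months and striatum of Q130 female 2 at 12 months correlated better with another tissue, so their values are not taken as those of the labelled tissue. ENSRNOG00000011073 stood apart at 2 months in the cerebellum of Q130 male 2 (80.6 CPM), the cortex of Q130 male 4 (106 CPM), the hippocampus of Q130 female 5 (113 CPM) and the striatum of Q130 male 4 (96.8 CPM). At 6 months it did so in the cerebellum of WT male 5 (179 CPM), the cortex of WT male 4 (72.3 CPM), the hippocampus of WT male 3 (153 CPM) and the library labelled striatum of Q130 male 1 (154 CPM), and at 12 months in the library labelled striatum of Q130 female 2 (147 CPM). ENSRNOG00000010867 stood apart at 2 months in the cerebellum of Q130 male 1 (3.27 CPM) and the hippocampus of WT female 5 (5.83 CPM), at 6 months in the cerebellum of Q130 male 3 (0.437 CPM) and the hippocampus of WT female 5 (2.95 CPM), and at 12 months in the striatum of Q130 male 3 (2.72 CPM). ENSRNOG00000005700 stood apart at 2 months in the cortex of Q130 male 4 (239 CPM) and the hippocampus of Q130 female 5 (216 CPM), at 6 months in the cortex of WT male 4 (273 CPM) and the hippocampus of WT male 3 (193 CPM), and at 12 months in the cortex of Q130 male 4 (132 CPM) and the striatum of Q130 male 3 (106 CPM).

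Genotype effects that differed between ages or tissues by a planned test of the difference were those on 11 striatal genes and 1 cerebellar gene at 12 against 2 months. At 2 months those on 22 genes differed between the striatum and the other tissues. The effect on striatum-enriched genes also differed at 12 against 2 months (-0.51 in all libraries and -0.25 without those that stood apart). That test was chosen after the pattern had been seen, its p was not adjusted, and the gene group differed between the ages. At 12 months the genotypes shared no first part of the animal identifier.

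The repeat libraries were mostly closest to an animal other than the one on their label, with 2 of 12 closest to the first library of their label. A difference between sequencing batches is argued against, since the median of the highest correlations with a first library was 0.94, where a batch effect strong enough to hide the animal would leave no first library with a high correlation. An exchange of the columns of first and repeat libraries is argued against as well, since 12 of 12 first libraries were closest to their own animal's other tissues, also over 46 genes chosen without any striatal library. Genotype labels that follow the animal are argued against for the repeats, since the difference in ENSRNOG00000011073 between labels was 0.14 of that in the first libraries. Each repeat was closest to a different first library, at a correlation of 0.90 to 0.97, with a second highest of at most 0.78. The median squared difference was 2.67 to 4.42 times counting noise from the closest first library, and 2.84 to 14.3 times from that of the same label. These values argue against labels that name the right animal, for the repeats not closest to their own label. A change of labels among the 12 repeats, by animal but not by tissue or batch, would give such values. How the labels came to differ was not tested, nor was any biological explanation.

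Some study libraries were out of place in their tissue. For the libraries labelled striatum of Q130 male 1 and hippocampus of Q130 male 5 at 6 months, which are labelled as tissues of the same animal, partial contamination by the other tissue is argued against, since genes of the labelled tissue fell by 3.67 log2 units or more below the group median. An exchange of their tissue labels is consistent with the differences in median correlation, own tissue minus the other, of -0.048 or lower in both. In the library labelled striatum of Q130 female 2 at 12 months, genes specific to males were at 5.32 log2 CPM, where the next female library was at -0.51 and males ran from 5.53 to 7.14, and hippocampus-enriched genes were raised, so that a sample mixed with hippocampus of a male is a candidate explanation. The other libraries that stood apart correlated best with their own tissue, their cause was not tested, and no biological explanation was tested for any.

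The genes called by genotype in the striatum at 2 and the cerebellum at 12 months were set against library size and the regional content of the dissected tissue. For these genes, library size is argued against by totals of 34.7 M counts on average in WT and 34.9 M in Q130 striatum and 30.8 and 31.8 M in the cerebellum (permutation p = 0.957 and 0.525). With totals this close, log total count as a covariate had little to remove, and its ratios of log2 fold changes, 0.999 and 1.03, are no further evidence. The cerebellum at 6 months was not tested in this way. Its totals averaged 33.9 ± 3.65 M counts in WT and 38 ± 3.92 M in Q130 rats (SD, n = 10 each), so library size stays open for the genes called there. For the cerebellum at 12 months, the ratio was 0.922 with the scores of cerebellum- and cortex-enriched genes as covariates (quartiles 0.828 and 1.05). These scores differed between the genotypes by -0.06 and 0.07 in the mean, so as covariates they may have had little to remove. The ratio is therefore only weak evidence against the regional content that they capture as the whole cause. Tissue from outside the 4 sampled regions is not covered, so regional content in general stays open. The median absolute log2 fold change went from 0.22 to 0.19 and the SE from 0.05 to 0.06. With smaller folds and a larger SE, 0 genes were then called. For the cerebellum-enriched score, 0 of 10 Q130 libraries lay above the WT median (difference -0.06, two-sided exact permutation p = 0.438). For the cortex-enriched score 8 of 10 did (difference 0.07, two-sided exact permutation p = 0.0722). For the striatum the ratio was 0.593 (quartiles 0.426 and 0.787), neither low enough to argue for it nor high enough to argue against it, with the median going from 0.18 to 0.10 and the SE from 0.04 to 0.05 and 1 gene called, and the reference age of the scores was changed after a first run. A larger share of striatal tissue in the Q130 samples of 2 months and an effect of the genotype on striatal genes cannot be told apart there, because the scores are made from genes that either would move, and the genotype effect itself stays open in both tissues.

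Other splits of the same samples were used to ask whether chance could give as many called genes. The bound set beforehand was a share of splits under 0.05. Meeting it does not exclude chance, and the shares were not adjusted over the comparisons. For genotype the bound was met in the striatum at 2 months, where 2 of 100 splits gave at least the real 393, the real one included. The highest other split gave 1005. It was also met in the cerebellum at 12 months (2 of 100, real 238, highest other 468) and at 6 months (1 of 100, real 44, highest other 4). In the cortex at 2 months it was met as well (2 of 100, real 1, highest other 1). At 12 months the splits also mixed first parts of the animal identifier that the genotypes did not share. A real count of 0 is reached by every split by construction, so the splits say nothing about chance there, and only their values are given. With 100 of 100 splits, the highest others were 2 and 1 in the striatum at 6 and 12 months, 0 and 17 in the cortex at 6 and 12 months, 1, 1 and 133 in the hippocampus at 2, 6 and 12 months, and 1 in the cerebellum at 2 months. Splits with several times the real count, here and among those that follow, point to a structure of the samples that was not tested.

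For the sums over tissues the bound was met (1 of 60 splits, real 3, highest other 1). For genotype by age it was met in the striatum at 12 against 2 months (1 of 30, real 11, highest other 1), but not in the cerebellum (2 of 30, real 1, highest other 4). The real count was 0, with 30 of 30 splits, in the striatum at 6 against 2 months (highest other 0) and 12 against 6 months (highest other 460), the cortex (highest other 1) and the hippocampus (highest other 0). For genotype by tissue the bound was met at 2 months (1 of 22, the smallest share possible, real 22, highest other 5). The real count was 0 at 6 and 12 months (22 of 22 splits, highest others 7 and 4). For genotype by sex the real count was 0 in each tissue (30 of 30 splits), with a highest other of 1 in the striatum and 0 elsewhere. The bound was met for ageing in WT rats, with 1 of 100 each, in the striatum (real 2658, highest other 864), cortex (550 and 40), hippocampus (2643 and 358) and cerebellum (3034 and 1211). It was also met for the batch comparison (1 of 100, real 633, highest other 12) and for age among batch 2 males (1 of 100, real 812, highest other 0). Both of these rest on the labels of the repeats, of which 2 of 12 were closest to the first library of their label. For genotype among the repeated males the bound was not met in batch 1 (9 of 100, real 1, highest other 18), and the real count was 0 in batch 2 (100 of 100, highest other 2).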

How the results depend on the processing

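Fits without the 9 libraries that stood apart, with library quality weights, with the repeat in place of the first libraries, and of the summed counts were chosen only after the results had been seen. The gene lists fixed beforehand, with their estimated-correlation and fry alternatives, were not run, since they need gene symbols. Counts stayed within 1.5 times in 12 of 12 results with a stricter filter, 33 of 34 with RLE, 29 of 34 without a filter, 28 of 32 with limma-voom, 12 of 13 with the identifier prefix, 11 of 12 without the sex covariate, 5 of 13 with DESeq2, 5 of 12 in 1 fit per tissue, 4 of 12 with quality weights and 10 of 21 without the libraries that stood apart. A result of 0 in both fits was counted as within 1.5 times, and many of these results were 0, so the tallies say little about stability there. The identifier prefix was not shared between genotypes at 12 months and hardly at 6 months, so the fit with it cannot separate prefix from genotype at those ages. Where no cause is given below, the cause was not tested. With the depth, spread and number of libraries of the striatum, the simulations recovered 77.6, 53.7 and 28.4% of genes changed by 0.32 log2 units, the smallest change simulated, at 2, 6 and 12 months, so a low count does not show that changes of that size are absent. Depth was not separated from the other limits.

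DESeq2 called 1013, 2 and 5 genes in the striatum at 2, 6 and 12 months, 1 in the cortex at 12 months, 1 and 1 in the hippocampus at 2 and 12 months, and 385 and 659 in the cerebellum at 6 and 12 months. Quality weights gave 1421, 1 and 3 in the striatum at 2, 6 and 12 months, 1 in the cortex at 6, 1 and 2 in the hippocampus at 2 and 6, and 1 and 293 in the cerebellum at 2 and 6 months. The fit over 60 libraries, which kept those that stood apart in each tissue, gave 1, 2 and 673 in the striatum and 0 in the cortex at 2 months. It gave 2 in the hippocampus at 6 months, and 3 and 45 in the cerebellum at 6 and 12 months. Without the libraries that stood apart, there were 1 and 1 in the striatum at 6 and 12 months, 1 in the cortex at 6 months and 2 in the cerebellum at 2 months. For genotype by age those fits gave 73 and 775 in the striatum at 6 and 12 against 2 months and 221 in the cerebellum, for genotype by tissue 124 and 6 at 2 and 12 months, for ageing in WT cortex 1688 and among batch 2 males 4056. With no filter there were 10 in the cerebellum at 6 months, 105 at 12 months, 10 in the summed counts, 5 for genotype by tissue at 2 months and 503 for age among batch 2 males. limma-voom called 9 in the cerebellum at 6 months, 9 with the identifier prefix, 6 and 0 for genotype by age in the striatum and cerebellum at 12 against 2 months, and 5 for genotype by tissue at 2 months. RLE gave 12 and no sex covariate 11 in the cerebellum at 6 months. With the repeat libraries in place of the first, the striatum at 2 months had 0, with 1567 at an unadjusted p under 0.05, but 2 of the 12 repeats were closest to the animal of their label and the fit mixed batches, so this count does not bear on the real one.

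With the replicate number as a block, counts were 259 in the striatum at 2 months, 18 and 125 in the cerebellum at 6 and 12 months and 0 among the repeated males of batch 1, and within 1.5 times in the other 10 of 14 results. The numbers share only a number: same-numbered libraries correlated at -0.24 to 0.57, all pairs were above 0.1 in 0 of 12 comparisons, and 28 of 120 were closest to their own number.

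Leaving out each library gave 79 to 1159 in the striatum at 2 months, with more than a 1.5-fold shift for 15 of 20, all but Q130 female 5, male 2 and male 4 and WT male 2 and male 3. It gave 4 to 471 in the cerebellum at 6 months (19 of 20, all but Q130 female 4) and 50 to 446 at 12 months (16 of 20, all but Q130 female 4 and male 4 and WT female 3 and male 2). Ranges were 0 to 1 in the striatum at 6 (1 without Q130 male 1) and 12 months (1 without Q130 female 2 or WT female 1), 1 to 1, 0 to 1 and 0 to 1 in the cortex at 2, 6 (1 without WT male 4) and 12 months (1 without WT female 2), 0 to 1, 0 to 0 and 0 to 0 in the hippocampus at 2 (1 without Q130 female 5), 6 and 12 months, and 0 to 1 in the cerebellum at 2 months (1 without Q130 male 2). Among the repeated males they were 0 to 3 in batch 1, with 0 without Q130 male 1 or WT male 4 of 2 months and 2 and 3 without WT male 2 and male 5 of 6 months, and 0 to 0 in batch 2.

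ENSRNOG00000011073 kept its direction in every setting. Estimates that changed sign belonged to genes not called. ENSRNOG00000005700 went from -0.05 in the striatum at 12 months to 0.04 with quality weights and 0.03 without the libraries that stood apart (-0.08 to 0.02 without single libraries), from -0.02 in the cortex at 6 months to 0.04 and 0.05 (-0.04 to 0.05), and from 0.01 in the cerebellum at 2 months to 0.00 with the replicate block, 0.00 with limma-voom, 0.00 with the prefix, -0.01 with quality weights and 0.00 without the libraries that stood apart (-0.04 to 0.05). ENSRNOG00000010867 in the hippocampus at 6 months went from 0.04 to -0.07 with quality weights and -0.03 without the libraries that stood apart (-0.03 to 0.08). Without those libraries, the median of striatum-enriched genes went from -0.36 to 0.01 in the striatum at 6 months, that of hippocampus-enriched genes from 0.34 to -0.03 there, from 0.18 to 0 in the striatum at 12 months and from -0.33 to 0 in the hippocampus at 6 months, and that of cerebellum-enriched genes from -0.05 to 0.01 in the cerebellum at 2 months.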

Other observations

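The test of the genes called at 12 months at the earlier age of 6 months and the tests of ageing genes were chosen only after the results they bear on had been seen; the test at 2 months was set beforehand.

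Genes that differed between 6 and 2 months in WT rats were followed in Q130 rats at 12 months. Age could not be told there from the first part of the animal identifier. In the cerebellum, 963 of 1462 genes that were higher at 6 than at 2 months in WT rats had lower estimates in Q130 than in WT rats at 12 months, with a median log2 fold change of -0.04 (camera adjusted p = 0.000388; adjusted p = 0.557 with an estimated correlation), and 899 of 1546 genes that were lower at 6 months had higher estimates, with a median of 0.02 (camera adjusted p = 0.0542, or 0.0325 when adjusted with the fits without the striatal and cortical libraries that stood apart; adjusted p = 0.555 with an estimated correlation). In the hippocampus 787 of 1308 genes lower at 6 months had higher estimates in Q130 rats, with a median of 0.01 (camera adjusted p = 0.0383; adjusted p = 0.749 with an estimated correlation), and 754 of 1317 genes higher at 6 months had lower estimates, with a median of -0.01 (camera adjusted p = 0.129). In the striatum 834 of 1351 genes lower at 6 months had higher estimates, with a median of 0.03 (camera adjusted p = 0.0599), and 664 of 1289 genes higher at 6 months did, with a median of 0 (camera adjusted p = 0.871). Without the 2 striatal libraries that stood apart, both striatal groups passed with higher estimates in Q130 rats: 821 of 1354 genes lower at 6 months, with a median of 0.02 (camera adjusted p = 0.0325), and 793 of 1292 genes higher at 6 months, with a median of 0.03 (camera adjusted p = 0.00682). Neither passed with an estimated correlation (adjusted p = 0.555 for both). The cortical groups of 259 and 285 genes had medians of 0 (camera adjusted p = 0.614 and 0.871).

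A hypothesis from the cerebellum was that the genes called at 12 months already differ at earlier ages in other animals. At 6 months 218 of 237 of them moved in the same direction, with a median signed log2 fold change of 0.10 (fry p = 0.00257), which is consistent with a difference also present at 6 months. At 2 months 150 of 236 did, with a median of 0.03 (fry p = 0.663), and 64 of 237 did without the 2 libraries that stood apart, with a median of -0.04 (fry p = 0.107). The bound written beforehand would have excluded a difference at 2 months, but a p above a threshold does not exclude a smaller difference, so that age stays open.

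Across the 12 comparisons of tissue and age, 25 of 14383 genes tested in all of them had the same sign in all 12, where 7.02 would if the comparisons were independent. The tissues of an animal are not independent, and the number expected with shared animals was not computed.

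Some genes were present in some animals and nearly absent in others, in all tissues. For the gene with the widest difference, every animal had a mean of at most -1.11 or at least 4.54 log2 CPM over its tissues, and 25 of 60 animals were high, 12 of 30 WT and 13 of 30 Q130 (two-sided Fisher's exact p = 1). In all, 14 genes had more than 0.9 of their variance within a tissue between animals.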
